A study of Homo sapiens with 6 samples.

How the data were processed

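Total RNA of 786-O cells was extracted with Trizol and sequenced from BGISEQ-500 libraries, per the labels' protocols. The 6 libraries form 2 groups of 3, Vehicle and XMU_MP_1, taken from the treatment labels, and each replicate number comes from the sample title. The labels describe the exposure to XMU_MP_1 as a transfection and give neither dose nor time.

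The authors deposited 1 table per library with FPKM (fragments per kilobase of transcript, scaled to the library's total) for 17114 gene symbols, to 2 decimals, per the file headers. The genome build is GRCh38, per the submitters' processing notes. The aligner, the quantifier, the annotation and any filter are not given in the sources used here. The tables list the same symbols, with no genes of the mitochondrial genome, and 37 genes are at 0 in every library. Because FPKM of a library is relative to its own total, a change in a few very abundant genes shifts all the others. The summed FPKM were 484517, 454889 and 487218 for Vehicle replicates 1 to 3 and 502040, 495351 and 527709 for XMU_MP_1 replicates 1 to 3. They are not depths. The values are not whole multiples of a shared unit, and read counts were not recovered. The smallest value of the H3 histone genes above a low cut-off was taken in each library. It ran from 0.11 to 0.21 FPKM, with a median of 0.11. If that value stood for 1 fragment and the full transcript length of 411 nucleotides was used, it would correspond to about 22100000 fragments, which is a rough figure. Depth per library is therefore treated as unknown, and no count model was used.

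Each gene was tested with limma (version 3.58.1, statmod 1.5.0, R 4.3.3) on log2(FPKM + 1), with group as the only term, a mean-variance trend and robust variance moderation. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 11151 in all, with no rescaling between libraries. P-values are two-sided and were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Log2 changes are XMU_MP_1 minus Vehicle. In total 34 gene lists were fixed before the data were examined. They were compared with all other tested genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the lists with at least 3 tested members, and again with a correlation estimated from the data. None of the 13 lists that passed with the preset value passed with the estimated one. The self-contained test fry asks whether the genes of a list move one way on balance and does not compare it with other genes. It gave adjusted p = 0.00389 for YAP/TAZ-TEAD targets and 6.13e-05 for NF-κB targets. Lists that did not pass camera also had low fry adjusted p, such as p53 targets (2.97e-04), cholesterol synthesis (2.7e-04) and HIF targets (0.00134). Hippo pathway components did not (0.84). Fry therefore does not single out the YAP/TAZ-TEAD and NF-κB targets. Shares of summed FPKM were compared by exact two-sided permutation tests.

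The rule for named genes was also fixed beforehand. It takes 12 core Hippo and NF-κB genes, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with no overlap between groups and a mean of at least 2 FPKM, and up to 4 members of each list with the smallest adjusted p. Other genes named in the text were chosen after their values were seen, and some genes that the rule takes are not reported here. Gene positions are those of GENCODE release 29 on GRCh38, matched by symbol or older symbol for 97.72% of the listed genes and 99.37% of the tested genes. The genes whose positions are given are all protein-coding, and the positions span the whole gene.

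Replicates were compared before use. Over 3950 genes with at least 20 FPKM, log2 differences between libraries had an SD of 0.093 for Vehicle replicates 1 and 3 and of 0.072 for XMU_MP_1 replicates 1 and 2. The other pairs within a group had SDs of 0.146 to 0.158, and pairs between groups of 0.377 to 0.452. Squared differences were set against the counting noise at the rough depth above, over tested and annotated genes above a low limit of estimated reads. Their median for the 2 close pairs was 1.13 and 1.15 times that noise. In genes with over 5000 estimated reads in the 2 libraries together, where counting noise is smallest, it was 3.13 and 3.83 times. The other pairs within a group had 2.9 to 4.08 and 19.45 to 26.33 times. Because the depth is rough, whether the close pairs differ by more than counting error is not settled. Each library was counted separately, and an alternative averages the close pairs.

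The scripts were tested on simulated data with 11151 genes and 200 changed genes for the comparison of XMU_MP_1 with Vehicle. The test recovered 20.4% of changes of log2 size 0.25, 79.6% of size 0.5 and 97.8% of size 1, and 4.19% of the calls were false. Camera passed a shifted list in 20 of 20 simulated data sets and an unchanged list in 0 of 20. The simulated genes varied independently of each other, so this does not test camera on lists whose members vary together. Each simulation changed 200 genes, against 6453 called in the data, so the recovery rates need not hold for these data. Alternatives planned beforehand were the replicate number as a block, median-of-ratios scaling, quantile normalization, sample weights, no filter on low values, a minimum mean of 5 FPKM, a pseudocount of 0.1, a minimum fold of 1.5 (limma's treat), each library left out in turn, and the estimated correlation. Alternatives chosen after seeing the data were the removal of trends with transcript length and GC content by splines with 4 degrees of freedom, the omission of the 2 libraries that stand apart within their group, the averaging of the close pairs, and a block for the 2 sides of the next principal axis, which is optimistic because the block was chosen from the same values. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.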

Results

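RNA of 786-O cells, an established human clear cell renal carcinoma line, was sequenced after exposure to a vehicle or to XMU_MP_1, with 3 libraries in each group. XMU-MP-1 is known as an inhibitor of the Hippo pathway kinases MST1 and MST2, which are encoded by STK4 and STK3. In that pathway these kinases restrain YAP and TAZ (the products of YAP1 and WWTR1), coactivators that bind TEAD transcription factors. The title of the study names YAP, a complex of TEAD4 with NF-κB, and tumour growth, so the single comparison asks how the inhibitor altered transcript levels in these cells, and in the Hippo and NF-κB genes in particular. The dose and the time of exposure are not given in the sources used here. Values are FPKM for 17114 gene symbols. Sequencing depth is not stated, and the summed FPKM of the libraries ran from 454889 to 527709. Means are given ± SD with n = 3 per group. Fold changes called log2 are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and ratios of mean FPKM are given as folds. For every gene named here as having risen or fallen, the 3 libraries of either group lay all above or all below the 3 of the other. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

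XMU_MP_1 shifted the transcriptome broadly but mostly by small amounts. Of 11151 genes tested with limma, 3567 were higher and 2886 were lower with XMU_MP_1 at a Benjamini-Hochberg adjusted p below 0.05, and 4698 did not pass. On the log2(FPKM + 1) scale 82 genes rose and 305 fell at least 2-fold, so large changes were more often decreases. The cytokine genes CCL2, CSF2 and LIF, the EGF-family ligand gene EREG and the death ligand gene TNFSF10 were among the genes that fell, and CCN2, IL11, CDKN1A, HEXIM1, the metallothionein gene MT2A and several histone genes were among those that rose. Values of the groups did not overlap for 7101 genes (63.7%), against 10% by chance for 3 libraries against 3. The main axis of a principal component analysis held 86.2% of the variance and separated the groups. The next axis held 7.1% and ran across the groups, with Vehicle replicate 2 (-8.6) on the side of XMU_MP_1 replicates 1 and 2 (-4.6 and -5.4), and XMU_MP_1 replicate 3 (9.5) on the side of Vehicle replicates 1 and 3 (4.7 and 4.3). With these sides as a block, chosen after seeing the data and from the same values, 4242 genes were higher and 3339 lower. With the closest pair of libraries of each group averaged, since these pairs differed by little more than estimated counting error over all genes compared, 2739 genes were higher and 2417 lower. Without Vehicle replicate 2 and XMU_MP_1 replicate 3, which stand apart from the close pair of their own group, like the averaging an alternative chosen after seeing the data, 4010 genes were higher and 3170 lower. Tested against a minimum fold of 1.5 in place of any change, 158 genes were higher and 455 lower.

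**Figure D1:**
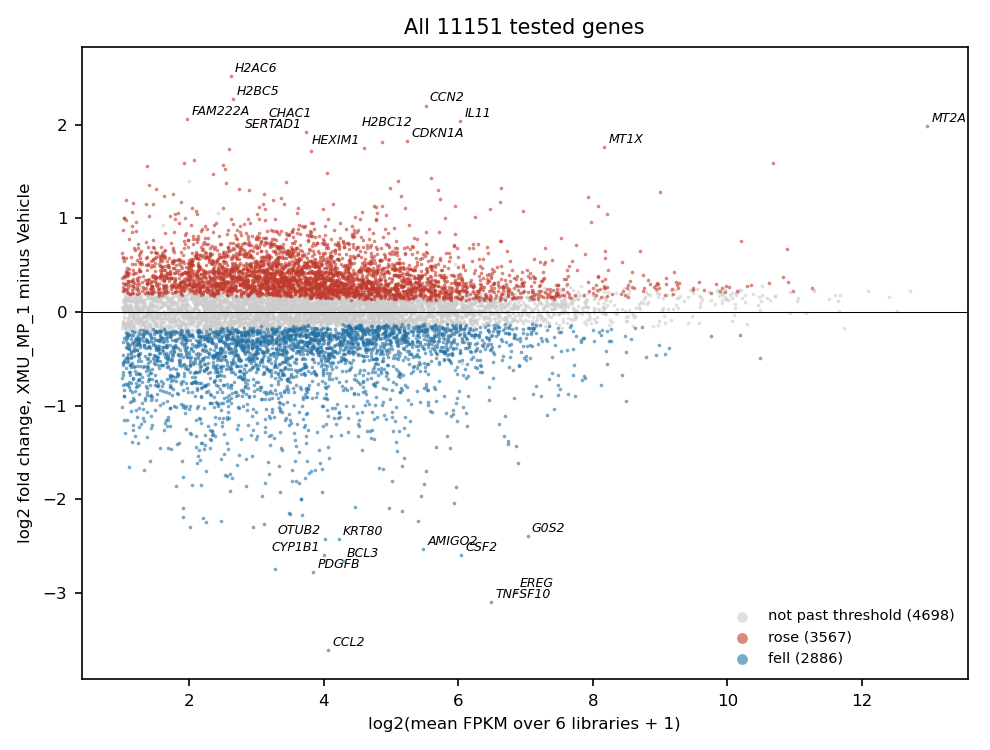
Log2 fold change on the log2(FPKM + 1) scale, XMU_MP_1 minus Vehicle, of each of the 11151 tested genes against the log2 of its mean FPKM + 1 over all 6 libraries. Red points are the 3567 genes that rose, blue points the 2886 that fell, grey points the 4698 that did not pass the threshold, and names mark the 12 largest rises and genes among the 12 largest falls, from H2AC6 at 2.52 to CCL2 at -3.61.

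Transcripts of the kinases that the inhibitor targets rose, and those of the coactivators downstream of them fell. STK3 (chromosome 8, 98371228 to 98942827, GRCh38) went from 8.97 ± 0.536 to 16.7 ± 0.686 FPKM, a log2 change of 0.83 ± 0.063 (SE, limma adjusted p = 1.56e-06). STK4 (chromosome 20, 44966474 to 45079959) went from 7.86 ± 0.409 to 11.5 ± 1.67 FPKM (adjusted p = 0.00107). YAP1 (chromosome 11, 102110461 to 102233423) fell from 22.7 ± 1.49 to 15.2 ± 1.76 FPKM, a log2 change of -0.55 ± 0.082 (adjusted p = 2.01e-04). WWTR1 (chromosome 3, 149517235 to 149736714) fell 1.98-fold, from 60.6 ± 1.07 to 30.6 ± 1.19 FPKM (adjusted p = 1.06e-07). The tested TEAD genes did not pass in the main fit. TEAD4 measured 23.4 ± 1.16 against 26.1 ± 2.67 FPKM (log2 change 0.148, adjusted p = 0.106). It passed with the replicate number as a block (log2 change 0.148, adjusted p = 0.0358), without XMU_MP_1 replicate 2 (0.216, adjusted p = 0.0294) and, in a setting chosen after seeing the data, with length and GC trends removed (0.166, adjusted p = 0.0249), so its call depends on the processing. With the sides of the axis across the groups as a block both TEAD4 (0.204, adjusted p = 0.00452) and TEAD1 (-0.257, adjusted p = 0.00104) passed. In the main fit TEAD1 measured 12.5 ± 1.61 against 11.2 ± 1.78 FPKM (adjusted p = 0.281) and TEAD3 5.96 ± 0.392 against 5.43 ± 0.218 FPKM (adjusted p = 0.182). TEAD2, at means of 0.433 and 0.343 FPKM, was too low to be tested. Of 28 tested Hippo pathway components, 9 rose and 9 fell, the same counts as adjusted over the list alone. RASSF1, which encodes a partner of the MST kinases, rose 1.54-fold, and WWC1, which encodes the scaffold protein KIBRA, fell 1.99-fold. The list did not stand apart from other genes (camera adjusted p = 0.778), with a median log2 change of 0.02 and a mean of -0.03.

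Known targets of YAP, TAZ and TEAD went both ways. CCN2 (chromosome 6, 131948176 to 131951373) and CCN1 (chromosome 1, 85580761 to 85583962), matricellular protein genes often used as readouts of YAP, both rose. CCN2 went from 15.3 ± 1.18 to 74.1 ± 3.29 FPKM, a log2 change of 2.20 ± 0.064 (limma adjusted p = 1.62e-09), and CCN1 from 144 ± 3.27 to 339.9 ± 10.9 FPKM, a log2 change of 1.23 ± 0.055 (adjusted p = 3.57e-08). Of 42 tested target genes, however, 26 fell and 10 rose, the same counts as adjusted over the list alone. GADD45A, a growth arrest and DNA damage gene, rose 2.52-fold. GADD45B, AMOTL2 and LATS2, which also passed as higher, had log2 changes of 1.30, 0.89 and 0.38. TNS3, which encodes a focal adhesion protein, fell 4.73-fold from 19.3 ± 2.15 to 4.08 ± 0.434 FPKM, and AREG, TGFB2, TNS1 and THBS1 fell as well. ANKRD1, another common readout, had a log2 change of -0.19. The median log2 change of the list was -0.33, and the list lay lower than other genes (camera adjusted p = 0.00127). That call was lost with an estimated correlation between its members (adjusted p = 0.496 with an estimated correlation).

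**Figure D2:**
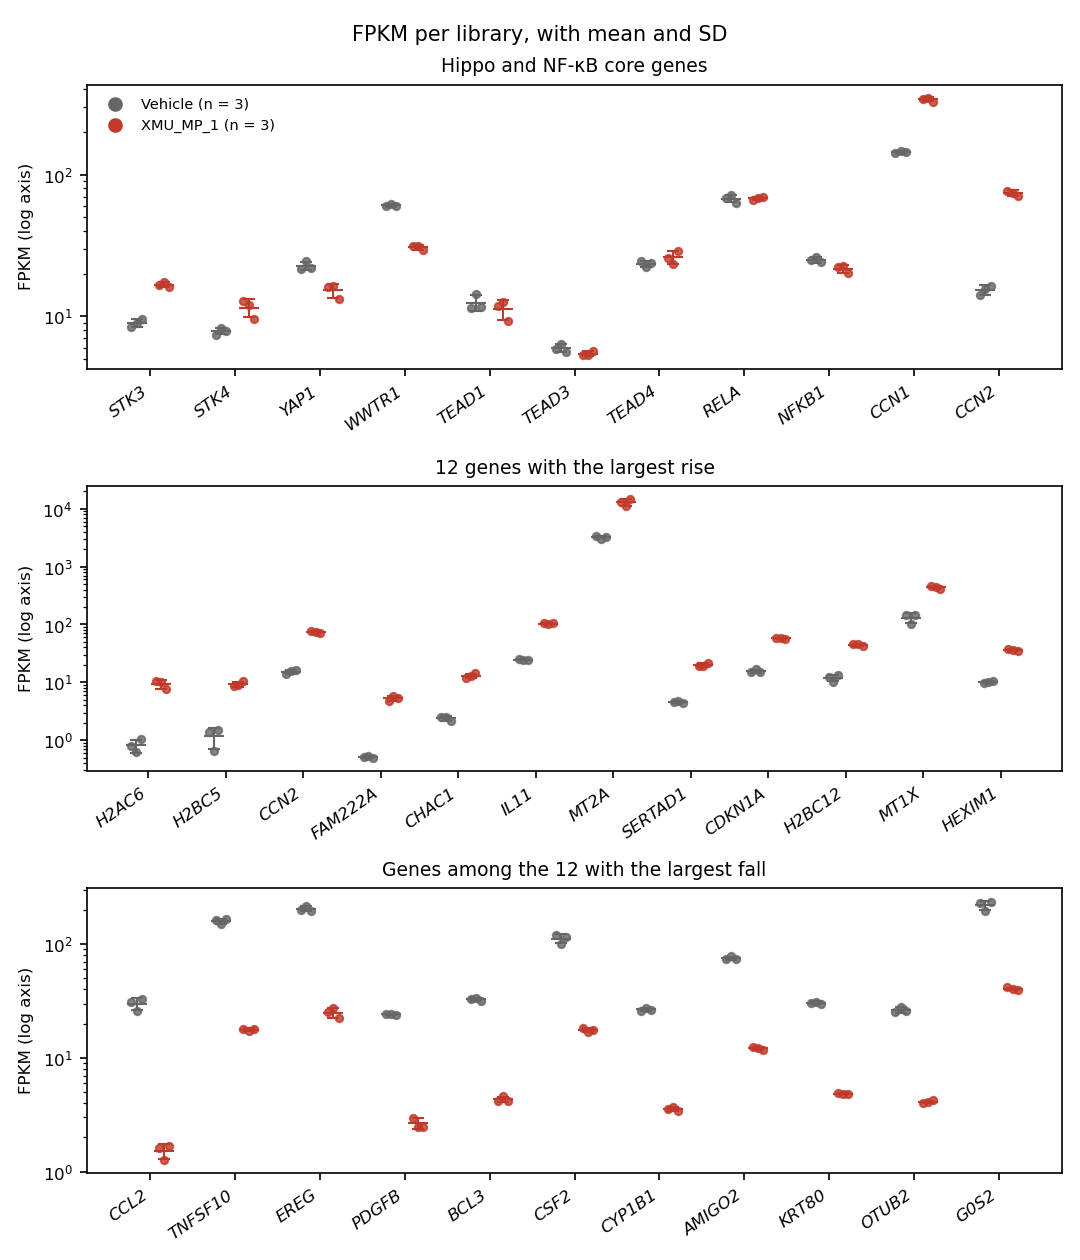
FPKM of each library on a logarithmic axis for the tested core Hippo and NF-κB genes, without TEAD2, and for the 12 genes with the largest rise and genes among the 12 with the largest fall, Vehicle in grey and XMU_MP_1 in red. Points are libraries, and bars give the mean and SD of 3 libraries. The groups overlap for TEAD1, TEAD3, TEAD4 and RELA and are apart for the other genes drawn.

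NF-κB target genes fell more often than they rose, while the transcript of the RELA subunit did not differ. RELA measured 67.8 ± 4.08 and 68.3 ± 1.72 FPKM (log2 change 0.01 ± 0.056, limma adjusted p = 0.868), and NFKB1 fell from 25.1 ± 1.12 to 21.7 ± 1.35 FPKM (adjusted p = 0.0156). Of 49 tested targets 32 fell and 6 rose, the same counts as adjusted over the list alone, and the median log2 change was -0.30. CCL2 (chromosome 17, 34255218 to 34257203), a monocyte chemokine gene, fell 19.7-fold from 29.9 ± 3.7 to 1.52 ± 0.218 FPKM, a log2 change of -3.61 ± 0.096 (adjusted p = 1.14e-09). BCL3, which encodes an atypical IκB protein, fell 7.57-fold, CSF2, which encodes the growth factor GM-CSF, fell from 112 ± 10.5 to 17.5 ± 0.771 FPKM, and PLAU, the urokinase gene, fell from 97.2 ± 3.45 to 25.8 ± 0.459 FPKM. The 6 that rose were IER3, SDC4, NFKBIA, CCL20, CXCL2 and NFKBIE, of which IER3, SDC4 and NFKBIA passed with the close pairs averaged and only IER3 against a minimum fold of 1.5. IL6 had a log2 change of 0.09 and SOD2 of 0.05, neither past the threshold. The list lay lower than other genes (camera adjusted p = 1.05e-05), with adjusted p = 0.224 with an estimated correlation. Of 19 NF-κB pathway components 8 fell, among them the adaptor gene MYD88 (1.83-fold) and the kinase gene IKBKB (1.52-fold), and 4 rose, among them RIPK1 (1.68-fold) and MAP3K7 (1.40-fold). The counts were the same adjusted over the list alone, and the list did not stand apart (camera adjusted p = 0.543).

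The 12 genes with the largest rise held 3 histone genes, 2 metallothionein genes and several regulators of growth and transcription. H2AC6 rose from 0.813 ± 0.206 to 9.47 ± 1.68 FPKM, H2BC5 from 1.17 ± 0.456 to 9.32 ± 0.908 and H2BC12 from 12.0 ± 1.62 to 44.3 ± 1.5. In the list of histone genes 6 of 8 tested members rose and 0 fell, the same counts as adjusted over the list alone. Its median log2 change was 1.33 (camera adjusted p = 0.00121, and adjusted p = 0.207 with an estimated correlation). HEXIM1 (chromosome 17, 45148502 to 45152101), which encodes an inhibitor of the transcription elongation factor P-TEFb, rose 3.6-fold from 10.1 ± 0.384 to 36.3 ± 1.85 FPKM (limma adjusted p = 4.17e-09). CDKN1A, which encodes the cell cycle inhibitor p21, rose 3.7-fold from 15.7 ± 0.889 to 58.0 ± 1.08 FPKM, SERTAD1 rose 4.41-fold, and FAM222A rose from 0.513 ± 0.0208 to 5.33 ± 0.521 FPKM. IL11, a cytokine gene of the IL-6 family, rose from 24.5 ± 0.454 to 103.7 ± 1.56 FPKM. MT2A rose from 3224 ± 154 to 12850 ± 1760 FPKM and MT1X from 131 ± 23.9 to 443 ± 25.2. Of the 8 tested genes in the metallothionein list 3 rose, MT2A, MT1X and MT1E, and MT1F fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.306, median log2 change 0.18). Metallothionein and histone genes have near-identical copies, and how shared reads were assigned is not given, so values of single members of these families are uncertain. H4C14 and H4C15, for example, held the same value in all 6 libraries.

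The 12 genes with the largest fall were led by CCL2 and by secreted factors. TNFSF10, which encodes the death ligand TRAIL, fell 8.99-fold from 159 ± 8.06 to 17.7 ± 0.468 FPKM (limma adjusted p = 1.73e-10). EREG, which encodes the EGF receptor ligand epiregulin, fell from 204.5 ± 11.3 to 24.97 ± 2.44 FPKM, and PDGFB, a platelet-derived growth factor gene, from 24.1 ± 0.405 to 2.66 ± 0.289. The cytochrome P450 gene CYP1B1 fell 7.47-fold, the deubiquitinase gene OTUB2 6.42-fold, the keratin gene KRT80 6.26-fold and the adhesion gene AMIGO2 6.19-fold. G0S2, which encodes an inhibitor of lipolysis, fell from 219 ± 19.7 to 40.6 ± 0.894 FPKM. BCL3 and CSF2 were also among the 12.

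Most listed genes of the integrated stress response rose. Of 25 tested genes of the ATF4 list 17 rose and 3 fell, the same counts as adjusted over the list alone, with a median log2 change of 0.41 (camera adjusted p = 0.00127, and adjusted p = 0.193 with an estimated correlation). CHAC1, which encodes a glutathione-degrading enzyme, went from 2.41 ± 0.223 to 13.0 ± 1.19 FPKM, the asparagine synthetase gene ASNS from 17.0 ± 0.792 to 44.1 ± 2.12, and ATF3 from 1.72 ± 0.0814 to 6.53 ± 0.3. VEGFA, also on this list, fell from 154 ± 6.17 to 57.4 ± 0.312 FPKM. The others that passed as lower were TRIB3, with a log2 change of -0.45, and STC2, with -0.23. Of 21 genes of the unfolded protein response 16 rose and 0 fell, also adjusted over the list alone, by less, with a median log2 change of 0.18 (camera adjusted p = 0.00241, and adjusted p = 0.318 with an estimated correlation). HERPUD1 rose 1.58-fold, SYVN1 1.56-fold and the sensor gene ERN1 2.42-fold. Of 19 heat shock genes 6 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.543, median 0.10). HSPA1B, whose near-identical copy HSPA1A had a log2 change of -0.23 that did not pass, rose 1.95-fold.

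Targets of p53 were divided. Of 28 tested targets 16 rose and 7 fell, or 16 and 8 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.165, median log2 change 0.40). CDKN1A and GADD45A rose, whereas GDF15, a stress cytokine gene, fell 10.3-fold from 6.53 ± 0.485 to 0.633 ± 0.0451 FPKM and PLK2 fell 1.79-fold. Among 24 apoptosis regulators 8 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.72, median 0.00 and mean -0.02). The BH3-only genes BCL2L11 and BMF, both of which encode promoters of cell death, moved apart. BCL2L11 rose from 1.98 ± 0.35 to 7.56 ± 0.286 FPKM and BMF fell from 5.1 ± 0.0987 to 0.427 ± 0.0603. The survival genes BCL2L1 and BCL2L2 fell 1.59-fold and 1.46-fold. Immediate-early and SRF target genes also went both ways, with 9 up and 9 down of 27, also adjusted over the list alone (camera adjusted p = 0.914 with the direction up, median -0.02 and mean 0.14). EGR1 rose 4.06-fold, IER3 2.43-fold and DUSP1 2.27-fold.

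Interferon-stimulated genes were lower, with 19 of 29 tested members down and 4 up, the same counts as adjusted over the list alone, and a median log2 change of -0.40 (camera adjusted p = 3.31e-04, and adjusted p = 0.193 with an estimated correlation). IFIT3 fell 4.44-fold from 12.7 ± 0.722 to 2.85 ± 0.104 FPKM, SAMD9L 3.12-fold and IFI44 2.27-fold. With genes limited to a mean of at least 5 FPKM the list no longer passed (camera adjusted p = 0.0636), and its median log2 change was smaller, at -0.274. Of 16 antigen presentation genes 8 fell, among them the regulator NLRC5 (2.18-fold) and the peptide transporter TAP1 (1.25-fold), and 3 rose, among them HLA-E (1.21-fold). These counts were the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.324, median -0.15).

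Matrix, junction and kidney lineage genes fell. Of 29 tested extracellular matrix and mesenchymal genes 19 fell and 0 rose (median log2 change -0.30, camera adjusted p = 2.01e-05, and adjusted p = 0.461 with an estimated correlation). THBS1, which encodes thrombospondin, fell 2.28-fold, TNC 1.74-fold, the matrix protease gene MMP14 1.58-fold and VCAN 1.48-fold. Of 15 epithelial and junction genes 10 fell and 1 rose (median -0.42, camera adjusted p = 4.11e-04, and adjusted p = 0.193 with an estimated correlation). The claudin gene CLDN1 fell from 153 ± 3.4 to 58.3 ± 3.02 FPKM, the keratin gene KRT19 from 218 ± 10.4 to 100.6 ± 6.07 and the connexin gene GJA1 2.1-fold. Of 11 renal tubule and carcinoma lineage genes 8 fell and 1 rose (median -0.82, camera adjusted p = 5.71e-04, and adjusted p = 0.193 with an estimated correlation). The kidney transcription factor gene LHX1 fell 2.5-fold, HAVCR1, the gene of kidney injury molecule KIM-1, fell from 43.6 ± 5.37 to 13.0 ± 1.59 FPKM, and VCAM1, an adhesion molecule gene also on the NF-κB list, fell from 96.9 ± 2.56 to 22.9 ± 2.4. Of 20 TGF-β target genes 11 fell and 3 rose (median -0.26, camera adjusted p = 0.0137, and adjusted p = 0.409 with an estimated correlation), with PMEPA1 down 2.19-fold, TGFB2 4.08-fold and LTBP2 2.89-fold. For these 4 lists the counts were the same adjusted over the list alone.

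**Figure D3:**
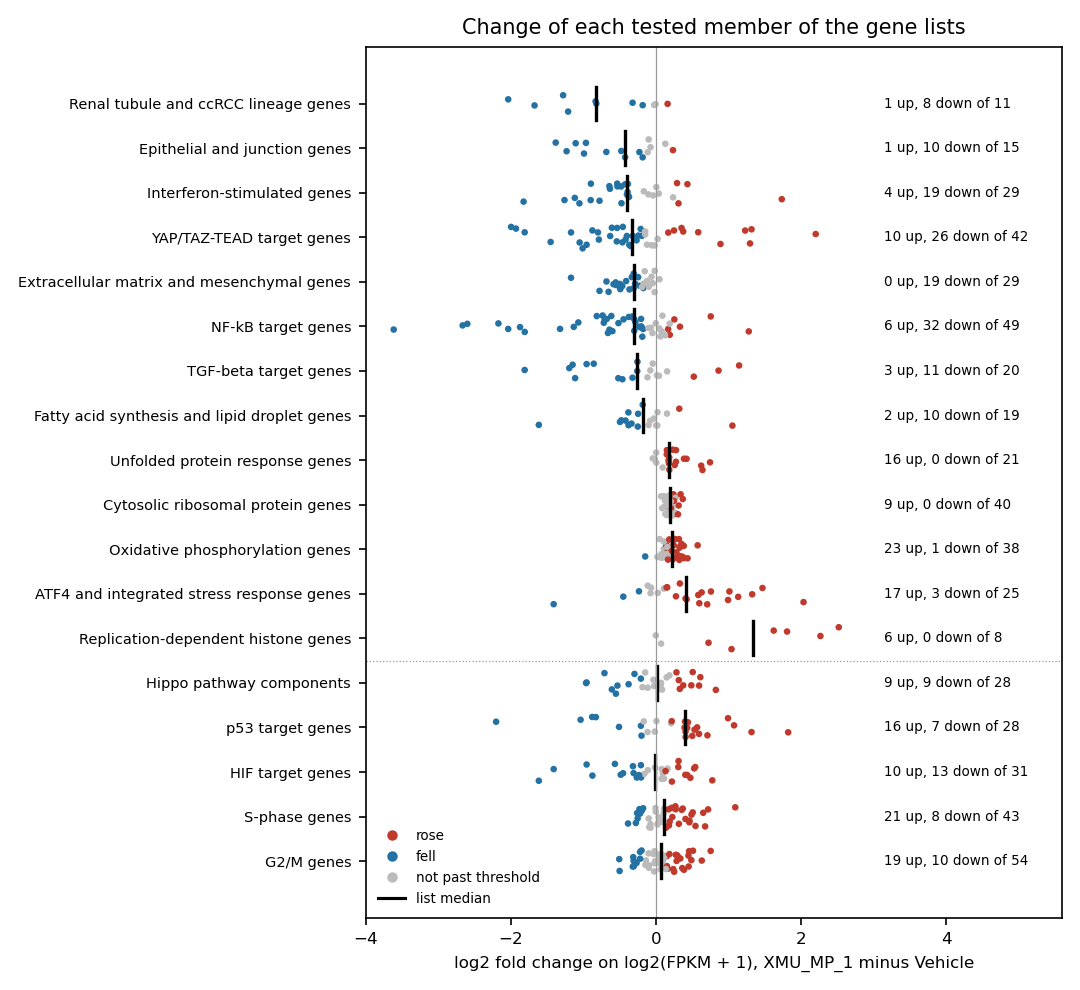
Log2 fold change on the log2(FPKM + 1) scale, XMU_MP_1 minus Vehicle, of each tested member of 18 gene lists, with members that rose in red, those that fell in blue, those not past the threshold in grey, and the list median as a black bar. The 13 lists above the dotted line passed the camera test with a preset correlation of 0.01, and none of them passed with an estimated correlation. Medians run from -0.82 for renal lineage genes to 1.33 for histone genes.

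Targets of the hypoxia-inducible factors, which are active in clear cell renal carcinoma, did not move together. Of 31 tested targets 13 fell and 10 rose, or 14 and 11 adjusted over the list alone (camera adjusted p = 0.44, median log2 change -0.01). The angiogenic factor gene VEGFA fell 2.69-fold and the lipid droplet gene PLIN2 fell from 177 ± 4.44 to 57.2 ± 0.961 FPKM, whereas the enolase gene ENO2 rose 1.75-fold. Of 8 HIF pathway components 3 rose and 1 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.647, median 0.16). The gene that fell was HIF1A, by 1.36-fold, and EGLN3 rose 1.77-fold. EPAS1, also on this list, had a log2 change of -0.097 that did not pass (limma adjusted p = 0.22). Of 19 fatty acid and lipid droplet genes 10 fell and 2 rose, also adjusted over the list alone (median -0.18, camera adjusted p = 0.0291, and adjusted p = 0.522 with an estimated correlation). DGAT1, a triglyceride synthesis gene, rose 2.15-fold, and the fatty acid elongase gene ELOVL6 fell 1.44-fold. The list no longer passed without Vehicle replicate 2 (camera adjusted p = 0.0887, median -0.153) or without XMU_MP_1 replicate 3 (camera adjusted p = 0.0601, median -0.203), with a median change of similar size.

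Nuclear genes of the respiratory chain were slightly higher, with 23 of 38 up and 1 down, or 24 and 1 adjusted over the list alone (median log2 change 0.22, camera adjusted p = 0.00121, and adjusted p = 0.664 with an estimated correlation). NDUFA2 of complex I rose 1.5-fold, COX6C of complex IV 1.31-fold and UQCRC2 of complex III 1.25-fold. Cytosolic ribosomal protein genes had a median log2 change of 0.20, with 9 of 40 up and 0 down but 0 up adjusted over the list alone (camera adjusted p = 0.0105, and adjusted p = 0.781 with an estimated correlation). The ribosomal list no longer passed without Vehicle replicate 2 (camera adjusted p = 0.115, median 0.097), without XMU_MP_1 replicate 3 (camera adjusted p = 0.123, median 0.138), or with quantile normalization (camera adjusted p = 0.616, median 0.043). Those libraries are the ends of the axis that runs across the groups, and they had the lowest and the highest mean of both lists. The remaining metabolic lists did not pass. Glycolysis genes had 6 up and 4 down of 19 (camera adjusted p = 0.843, median 0.03), with the glucose transporter gene SLC2A1 down 1.4-fold. Cholesterol synthesis genes had 7 up and 3 down of 24, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.62, median 0.06), with IDI1 up 1.41-fold and HMGCS1 down 1.3-fold. NRF2 targets had 6 up and 5 down of 20 (camera adjusted p = 0.66, median 0.12), with OSGIN1 up 1.84-fold and AKR1B10 down 1.62-fold. Autophagy and lysosome genes had 9 up and 5 down of 24 (camera adjusted p = 0.306, median 0.12), with MAP1LC3B up 1.66-fold and ULK1 up 1.92-fold and the lysosomal regulator TFEB down 1.92-fold. For the glycolysis, NRF2 and autophagy lists the counts were the same adjusted over the list alone.

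Cell cycle genes showed no uniform shift. Of 43 S-phase genes 21 rose and 8 fell (median log2 change 0.11, camera adjusted p = 0.0836), with the cyclin gene CCNE2 up 2.27-fold and the histone mRNA binding protein gene SLBP up 1.58-fold. The S-phase list passed without XMU_MP_1 replicate 3 (camera adjusted p = 0.0487) and with no filter on low values (camera adjusted p = 0.0178). Of 54 G2/M genes 19 rose and 10 fell (median 0.06, camera adjusted p = 0.44), with TUBB4B up 1.69-fold and the mitotic kinase gene AURKA down 1.43-fold. For both lists the counts were the same adjusted over the list alone. Of 28 MYC and ribosome biogenesis genes 3 rose and 9 fell, or 2 and 9 adjusted over the list alone (median -0.03, camera adjusted p = 0.306), with ODC1 up 1.45-fold and the dyskerin gene DKC1 down 1.32-fold.

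Fibroblast and endothelial markers were low in all libraries, and few other markers of foreign cell types could be tested. None of the 14 listed fibroblast and endothelial markers reached a mean of 1 FPKM, and their summed means were 2.79 FPKM in Vehicle and 1.87 FPKM in XMU_MP_1. Of 14 listed markers of other epithelial or melanocytic lines 1 was tested, GATA3, which fell from 2.95 ± 0.452 to 0.98 ± 0.0872 FPKM, also adjusted over the list alone. Of 14 listed haematopoietic markers 3 were tested and 2 fell, CSF1R and LAPTM5, also adjusted over the list alone (camera adjusted p = 0.206, median log2 change -0.30), while CD68, which many cell types express, measured 31.9 ± 0.979 and 31.7 ± 0.592 FPKM. LAPTM5 measured 9.19 ± 0.478 and 7.3 ± 1.0 FPKM and did not pass without Vehicle replicate 3 (limma adjusted p = 0.0521), without XMU_MP_1 replicate 1 (limma adjusted p = 0.0515) or with the close pairs averaged (limma adjusted p = 0.0632). Of the 13 genes encoded by the mitochondrial genome 0 were listed in the files. Metallothionein genes took 0.887% ± 0.0387 of the summed FPKM in Vehicle and 3.1% ± 0.272 in XMU_MP_1, and histone genes 0.0204% ± 0.000737 and 0.0474% ± 0.000961. The 10 most abundant genes took 8.46% ± 0.133 and 10.4% ± 0.442. Each of these 3 shares was higher in all 3 XMU_MP_1 libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Ribosomal protein genes took 13.3% ± 1.09 and 14.3% ± 0.713 (exact permutation p = 0.3).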

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

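The settings that removed length and GC trends, left out both libraries that stand apart within their group, averaged the close replicates or blocked on the shared axis were chosen after seeing the data. The number of changed genes, 6453 in all, stayed within 1.5 times in every setting except the test against a minimum fold of 1.5, which by construction asks for larger changes and gave 158 up, 455 down and 613 in all. Leaving out each library in turn gave 5606 to 6447 genes. Of the genes called in both the stated fit and an alternative, 0 had opposite directions in any setting. Median-of-ratios scaling moved the share of calls that were up from 55.3% to 49.6%. Of 138 tested named genes 133 passed, and 70 of these kept direction and call in every alternative that tests them. Most of the losses came from the minimum fold of 1.5.

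Whether the replicate numbers pair the samples is not settled. Deviations from the group means of same-numbered libraries correlated at -0.2, 0.39 and 0.24. The value of 0.39, for replicate 2, was the highest of all pairs between groups, but Vehicle replicate 1 correlated better with XMU_MP_1 replicate 3 (0.34). With the replicate block 3956 genes were up and 3093 down, 7049 in all, and all 13 lists that passed kept their calls. TEAD4 passed under the block (adjusted p = 0.0358) and with length and GC trends removed (adjusted p = 0.0249). With the sides of the shared axis as a block 4242 genes were up and 3339 down, TEAD1 (adjusted p = 0.00104) and TEAD4 (adjusted p = 0.00452) passed, and no list changed its call. The cause was not tested.

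With an estimated correlation no list passed. The camera adjusted p was 0.193 for the ATF4, epithelial, interferon and renal lineage lists, 0.207 for histone genes, 0.224 for NF-κB targets, 0.318 for the unfolded protein response, 0.409 for TGF-β targets, 0.461 for matrix genes, 0.496 for YAP/TAZ-TEAD targets, 0.522 for fatty acid genes, 0.664 for respiratory chain genes and 0.781 for ribosomal protein genes. By construction this form of camera uses the few residual degrees of freedom of the libraries in place of those of the genes. Lists whose members vary together are also penalised, but that does not account for the ATF4 and interferon lists, with estimated correlations of -0.027 and -0.03. Ribosomal protein genes also failed with quantile normalization (0.616) and with both libraries that stand apart left out (0.454), and leaving out each library in turn gave 0.00158 to 0.123, with 0.115 without Vehicle replicate 2 and 0.123 without XMU_MP_1 replicate 3. Fatty acid genes failed with both libraries left out (0.169), and leaving out each library gave 0.0174 to 0.0887, with 0.0887 without Vehicle replicate 2 and 0.0601 without XMU_MP_1 replicate 3. Interferon-stimulated genes failed with a mean of at least 5 FPKM (0.0636), where fewer members are tested and their median log2 change was -0.274 in place of -0.399. S-phase genes, which did not pass, did so with no filter (0.0178) and without XMU_MP_1 replicate 3 (0.0487). The cause was not tested for the ribosomal, fatty acid and S-phase lists. With a minimum fold of 1.5, members up and down were 5 and 9 for YAP/TAZ-TEAD targets and 1 and 11 for NF-κB targets. With the close replicates averaged 3 NF-κB targets were up, with fewer samples in the fit. Depth is unknown, so how far counting error limits genes with low values cannot be stated.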

Other observations

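The tests on capture of RNA without a poly(A) tail and on S phase were chosen after the results they bear on had been seen, as were the genes of the next paragraph, and the others were written down beforehand.

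Ligand genes of the same receptor family moved apart. Among ligands of the EGF receptor family, EREG fell 8.19-fold, AREG fell from 23.8 ± 2.95 to 5.52 ± 0.923 FPKM and BTC fell 1.56-fold, while HBEGF rose from 17.9 ± 0.234 to 48.7 ± 0.445 FPKM and TGFA measured 35.1 ± 1.88 and 32.5 ± 3.79 FPKM (limma adjusted p = 0.259). Among cytokines of the IL-6 family IL11 rose 4.23-fold, LIF fell from 49.0 ± 1.46 to 13.3 ± 0.399 FPKM, and IL6 measured 142 ± 5.44 and 152 ± 4.34 FPKM (adjusted p = 0.172). The hyaluronan synthase genes HAS2 and HAS3 both fell, HAS2 from 6.87 ± 0.359 to 0.657 ± 0.0929 FPKM and HAS3 from 68.6 ± 2.12 to 13.8 ± 1.13. The genes of the PD-1 ligands fell together, PDCD1LG2 from 8.17 ± 0.657 to 0.953 ± 0.11 FPKM and CD274 from 12.4 ± 0.267 to 6.19 ± 0.616. The activin subunit gene INHBA fell 4.59-fold, and the cytokine receptor gene IL7R fell from 5.12 ± 0.05 to 0.337 ± 0.0252 FPKM.

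Of the 10 splits of the 6 libraries into 3 and 3, only the real one (1 of 10) gave as many changed genes, 6453 against 0 in the highest other split. With 10 splits the share cannot fall below 0.05, so the splits are too few for that test. The other splits also mix the 2 groups, so any difference between the groups widens the spread within each side and lowers the calls. The contrast of 6453 with 0 therefore adds no evidence.

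HEXIM1, SERTAD1 and several H2A and H2B histone genes rose together, and rises of HEXIM1, SERTAD1 and histone genes are known from cells given inhibitors of BET bromodomain proteins. More cells in S phase would raise S-phase genes as well. The upper 95% bootstrap bound of their median log2 change was 0.23, around a median of 0.11, with genes and not libraries resampled. This was far less than 1.81 for H2BC12, 2.27 for H2BC5 and 2.52 for H2AC6 on the same log2(FPKM + 1) scale. Of 43 S-phase genes 21 rose and 8 fell, however. How strongly histone transcripts would rise with a given rise of S-phase genes was not measured, so this explanation is not set aside. For the histone genes, uneven capture of RNA without a poly(A) tail cannot be told apart, because the H3 and H4 genes lie near the floor. Their median log2 change on log2(FPKM + 0.1) had an interval from 0.18 to 1.33, with H4C14 and H4C15, equal in all libraries, counted separately. That interval spans 1.13, the bound set from the median of 2.25 of 7 H2A and H2B genes. These 7 were taken because they had passed as higher, so the bound itself rests on the rise. Of 7 tested genes known to respond to BET inhibitors that had not been looked at singly, 6 (85.7%) passed in the known direction, among them SERPINI1 and ZCCHC24 up and MYC, FOSL1 and CD274 down, while IL6 did not pass, where the overall rates of calls would give 1.99. A response like that to BET inhibitors is thus a candidate explanation and remains a hypothesis, since these genes also answer to other signals and action of the compound on other kinases or on MST1 and MST2 themselves was not tested.

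YAP1 and WWTR1 were lower. Of 42 tested YAP/TAZ-TEAD targets 26 passed as lower and 10 as higher, the 10 including CCN1, CCN2, GADD45A, GADD45B, AMOTL2 and LATS2. Trends with gene length and GC content do not account for this, since 97.2% of the called members (35 of 36) kept their call and direction once these trends were removed. Lower output of the ERK pathway, which shares targets such as AREG and EREG, cannot be told apart, because the ERK output genes had a median log2 change of -0.24 with 7 of 13 down and 1 up, and their members went both ways, as with ETV4 (-0.87) and ETV5 (0.59). A change in YAP activity caused by the inhibitor stays open and untested, as no measure of protein or binding was analysed here.

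Among short, abundant genes, 23 of 38 respiratory chain genes passed as higher with XMU_MP_1 but only 9 of 40 ribosomal protein genes did, 0 adjusted over the list alone, and differences between libraries of the kind seen within a group cannot be told apart for either list. With length and GC trends removed both lists still passed at the preset correlation (camera adjusted p = 0.0022 for respiratory chain and 0.0106 for ribosomal protein genes), and the mean of each list was higher in all 3 XMU_MP_1 libraries. For ribosomal protein genes the margin was small, with log2 means of 9.68 for XMU_MP_1 replicate 2 and 9.67 for Vehicle replicate 3. Without the removal both were 9.68. A kept call and no overlap had been set beforehand as evidence against this explanation. That criterion was too weak, because members of the lists vary together within groups, with estimated correlations of 0.624 and 0.941, at which neither list passed in the main fit (0.664 and 0.781), and the differences between groups were 1.81 and 1.21 times the larger SD within a group, or 2.06 and 1.34 times with the trends removed. A bound of 2 SDs was tried after the results were seen and not kept. It would have argued against this explanation for respiratory chain genes only, by a small margin and only with the trends removed (2.06). Without their removal the ratio of 1.81 lay below that bound. Without Vehicle replicate 2 and XMU_MP_1 replicate 3 the ribosomal list failed (0.454) and the respiratory chain list passed (0.0198), both passed at the preset correlation with the axis shared across groups as a block chosen from the same values (2.69e-08 and 2.00e-06), and an effect of the inhibitor on either list stays untested.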
